A study of Mus musculus with 6 samples.

How the data were processed

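Messenger RNA libraries of splenic γδ T cells were compared before (Initial) and after (Induced, day 8) culture, with 3 libraries per group. Per the labels' protocols, libraries were made with the VAHTS mRNA-seq v2 kit and sequenced on an Illumina instrument, and Cuffdiff gave FPKM values for coding genes in each sample. Per the submitters' processing notes, CASAVA, HISAT2 2.0.5 and Cuffdiff were used, with both 1.3.0 and 2.2.1 named for Cuffdiff, and the genome build mm9. The deposited FPKM tables do not carry mm9 positions: of the 26669 gene identifiers that were found in the GENCODE annotation of GRCm38, 90.46% lie inside the span the file gives and 99.94% on the same chromosome, so positions are given here from that annotation and that build. Whether the counting used strand is not given in the sources used here.

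Per the file headers, each deposited table lists a gene identifier, a symbol, a locus and an FPKM value for 1 library. No listed value is 0, so genes missing from a table were taken as 0, which can also mean that no estimate was made. Together the tables list 26771 genes, 13976 of them in all 6 libraries, and 24 symbols that had been turned into dates were restored from the gene identifier. Groups and mouse letters were taken from the sample titles. The labels name mice A, B and C in both groups, and these letters pair the libraries by animal. Correlations of the deviations from the group means between libraries of the same mouse were 0.0393, 0.0307 and 0.1308 for A, B and C. Between libraries of different mice they ran from -0.1324 to 0.0988. The highest of these, Initial B with Induced A, exceeded the values of A and B, so the pairing of these mice did not stand out. The cells of a pair were not handled alike, and each group was prepared in 1 way only, so group and handling coincide.

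Because the values are FPKM and not counts, they were tested on the scale of log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with a mean-variance trend and robust shrinkage, two-sided, without a block, and with Benjamini-Hochberg adjustment. A gene was called changed at an adjusted p under 0.05. Genes with an FPKM of at least 1 in at least 3 libraries were tested. Of the 29 gene lists written before the data were examined, the 26 with at least 5 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, with an estimated correlation and with fry as alternatives, and adjusted over the lists. The genes detected per library were compared with an exact permutation test. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

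The genes named in the report follow a rule written before the data were examined. It takes 10 fixed genes (of which Il17a, Il17f, Il22, Il23r, Il1r1, Ccr6, Ifng, Tbx21 and Csf2 are reported), and the 10 largest rises and 10 largest falls among genes with an adjusted p under 0.05, a mean FPKM of at least 20 in the higher group, no overlap between the groups and the same direction in each mouse. Immunoglobulin and T cell receptor segments, predicted genes, Rik clones, small RNAs and mitochondrial genes were passed over there. From each list it takes the 2 largest rises and 2 largest falls past the threshold. Of the genes the rule takes, 2 are not reported here.

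No counts were used, so depth was estimated from the low values. In genes with 1 annotated transcript, the product of FPKM and length came in steps of 1 fragment, and 41.0 to 51.0% of the low values lay within 0.15 of a whole multiple, where chance gives 30%, so the depths are rough. Between libraries of one group the variance was 2.44 to 5.64 times that of counting, so no library was a copy of another. The test was checked on simulated data for this comparison, with 10781 genes and 50 changed at each size. It recovered 42% of genes changed 1.5-fold, 80% at 2-fold, 96% at 4-fold and 100% at 8-fold, with 5 false calls among 164. In that simulation 10581 genes were unchanged, while 70.4% of the genes tested in the real data were called changed. Benjamini-Hochberg adjustment depends on the share of genes changed, so these rates do not give those of the real comparison.

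The alternatives were pseudocounts of 0.1 and 5, no filter and a filter at FPKM 5, scaling factors of the TMM kind written for this work, scaling to a common sum, quantile normalization, the mouse as a block, an ordinary moderated test and leaving out each library. After the data were seen, scaling to the T cell identity list, scaling to Cd3d, Cd3e, Cd3g, Cd247 and Trdc, and leaving out genes of other cell types, also from the number of genes detected, were added.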

Results

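The series measured messenger RNA of γδT17 cells, γδ T cells that make interleukin-17, from the spleens of C57BL/6 mice without the T cell receptor β chain. Cells sorted from splenocytes before culture, by a gate not given in the sources used here, form the Initial group, and cells harvested on day 8 of a culture based on IL-1β and IL-23 and purified by magnetic depletion form the Induced group. Each group held 3 libraries, from mice A, B and C, and the same letters occur in both. The deposited values were FPKM per gene, fragment counts scaled by transcript length and by library size. From the size of the smallest step between values, the depth was estimated at about 21400000 to 25100000 fragments in the Initial libraries and 22400000 to 27100000 in the Induced libraries. At an FPKM of 1, counting alone then gave a 2 kb transcript a coefficient of variation of 13.6 to 15.3%. All means below carry the SD over 3 libraries, all fold changes are on the log2(FPKM + 1) scale with their standard error (SE), and all adjusted p-values for genes are from limma with Benjamini-Hochberg adjustment. On that scale the change of genes with low values is understated.

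The comparison of Induced with Initial cells asked how culture changed the transcriptome of these cells. Most tested genes of the cell cycle, glycolysis and cholesterol and fatty acid synthesis lists rose after culture. Most of those of naive and recirculating lymphocytes, immediate early genes and markers of B cells, macrophages and red cells fell. Camera called these lists with its preset correlation but not with an estimated correlation (adjusted p = 0.221 to 0.311). Granzyme B (Gzmb) went from 47.0 ± 3.51 to 1062 ± 20.9 FPKM, and the nuclear receptor gene Nr4a1 from 868 ± 206 to 3.65 ± 0.625 FPKM. Of 11265 genes tested, 7931 changed, of which 4199 rose and 3732 fell. At least 2-fold changes were called for 2838 genes, with 1348 higher and 1490 lower in Induced cells, and for 1604 genes with a pseudocount of 5. The libraries of one group did not overlap those of the other for 8497 genes, or 75.4% of those tested, where chance gives 10% for 3 against 3. Correlations across genes, which are not independent replicates, lay between 0.986 and 0.996 within a group and between 0.786 and 0.827 between groups. The balance of rises and falls depended on the scaling of the libraries: 52.9% of the called genes rose with the values as deposited. With libraries scaled to the T cell identity genes, an alternative added after the data were seen, 85.1% rose. There 944 calls turned to the opposite direction, but that list itself fell, so the scaling raises other genes by construction. With libraries scaled to the CD3 chains and Trdc instead, 66.8% of the called genes rose and 0 calls turned.

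The genes of receptors that the culture cytokines act on rose. Il23r (ENSMUSG00000049093, chromosome 6, 67422932 to 67491855, GRCm38) went from 4.22 ± 1.10 to 26.4 ± 4.65 FPKM and Il1r1 (ENSMUSG00000026072, chromosome 1, 40225080 to 40317257) from 3.24 ± 0.261 to 18.8 ± 5.34 FPKM, with log2 fold changes of 2.40 (SE 0.17, adjusted p = 1.1e-05) and 2.18 (SE 0.20, adjusted p = 3.9e-05). Csf2 (ENSMUSG00000018916, chromosome 11, 54247271 to 54249667), which encodes the growth factor GM-CSF, rose from 0.710 ± 0.112 to 15.1 ± 2.79 FPKM, a log2 fold change of 3.22 (SE 0.14, adjusted p = 7.6e-07). Other genes of the same programme fell. Il22 (ENSMUSG00000074695, chromosome 10, 118204942 to 118210047) went from 4.72 ± 1.01 to 0.156 ± 0.0970 FPKM, Il17f (ENSMUSG00000041872, chromosome 1, 20777146 to 20790617) from 7.70 ± 2.81 to 2.50 ± 0.645 FPKM, and the chemokine receptor gene Ccr6 (ENSMUSG00000040899, chromosome 17, 8236043 to 8257141) from 4.42 ± 0.394 to 0.792 ± 0.166 FPKM. Their log2 fold changes were -2.30 (SE 0.15), -1.27 (SE 0.25) and -1.60 (SE 0.12), with adjusted p-values of 5.4e-06, 0.0027 and 9.9e-06.

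Il17a (ENSMUSG00000025929, chromosome 1, 20730905 to 20734496) itself did not pass the test. It stood at 10.4 ± 4.24 FPKM in Initial and 15.9 ± 7.54 FPKM in Induced cells, and was higher after culture in 2 of the mice (log2 fold change 0.51, SE 0.43, adjusted p = 0.325). Without Induced library C, which had 7.64 FPKM against 17.5 and 22.5 in the others, the log2 fold change was 0.93 and the adjusted p 0.0284. The type 1 cytokine gene Ifng (ENSMUSG00000055170, chromosome 10, 118441046 to 118445892) had 35.2 ± 7.25 and 42.9 ± 6.10 FPKM (log2 fold change 0.29, SE 0.16, adjusted p = 0.141), and its regulator Tbx21 (ENSMUSG00000001444, chromosome 11, 97098071 to 97115331) had 58.8 ± 10.4 and 82.5 ± 21.1 FPKM (log2 fold change 0.47, SE 0.19, adjusted p = 0.0643). Both were higher in Induced cells in each mouse, and with the mouse as a block their adjusted p-values were 0.0323 and 0.0052. Without Initial library B the adjusted p for Ifng was 0.0336, with a log2 fold change of 0.44. Both also passed with libraries scaled to the CD3 chains and Trdc (log2 fold changes of 0.51 and 0.69, adjusted p = 0.0335 and 0.0176). Scaled to the T cell identity genes, their log2 fold changes were 1.14 and 1.33 (adjusted p = 2.3e-06 and 1.8e-07).

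**Figure D1:**
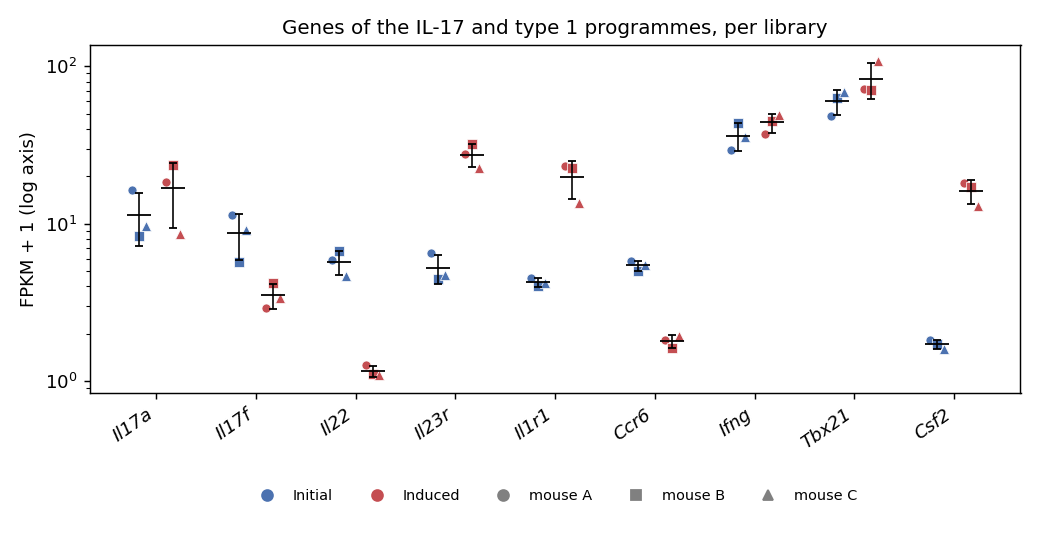
FPKM + 1 on a log axis of 9 of the 10 genes fixed before the data were examined, in 3 Initial (blue) and 3 Induced (red) libraries; marker shapes give the mouse, horizontal bars the mean and error bars the SD. Il23r, Il1r1 and Csf2 sit higher and Il17f, Il22 and Ccr6 lower in all Induced libraries, while Il17a and Ifng overlap between the groups.

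Of 24 tested genes in the list of type 17 genes, 13 rose, 6 fell and 5 did not pass, and camera did not call the list (adjusted p = 0.144). It was called without Induced library C (adjusted p = 0.0203), without a filter on low values (adjusted p = 0.00674) and with the filter at FPKM 5 (adjusted p = 0.0244). Tmem176b, a membrane protein gene, had the largest rise. It went from 35.6 ± 2.42 to 600 ± 150 FPKM. Tmem176b overlaps Tmem176a on the other strand, and how strand was handled is not given in the sources used here, so its level is uncertain. Sox4 (55.6 ± 5.47 to 0.225 ± 0.0809 FPKM) and the aryl hydrocarbon receptor gene Ahr (27.6 ± 5.47 to 1.52 ± 0.202 FPKM) had the largest falls. Of 24 genes of the type 1 and cytotoxic list, 6 rose, 10 fell and 8 did not pass (camera adjusted p = 0.537). Gzmb rose, with Gzmc at 1.43 ± 0.335 and 23.9 ± 13.3 FPKM, while the chemokine genes Xcl1 (131 ± 57.8 to 5.85 ± 2.69 FPKM) and Ccl5 (696 ± 154 to 162 ± 138 FPKM) fell. Induced library C had 320 FPKM of Ccl5, against 99.8 and 65.3 in A and B, and without it the log2 fold change went from -2.41 to -3.07. With libraries scaled to the T cell identity genes the call of Ccl5 was lost (adjusted p = 0.0616). The type 1 and cytotoxic list was called there (adjusted p = 0.0161). The type 2 and regulatory list had 7 tested genes, of which 6 fell, led by Areg (2.75 ± 1.43 to 0.127 ± 0.0773 FPKM) and Ccr8 (2.90 ± 1.25 to 0.393 ± 0.128 FPKM). Its camera adjusted p was 0.0349, against an adjusted p of 0.393 with an estimated correlation, 0.0673 without Induced library C, 0.347 without a filter on low values and 0.0587 after quantile normalization. Adjusted over the list alone, the counts of these 3 lists were the same.

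The largest rises by the fixed rule were those of Ifitm1, an interferon-induced membrane protein gene, and Iigp1, an interferon-induced GTPase gene. Ifitm1 went from 1.26 ± 0.299 to 220 ± 183 FPKM, with 162, 73.4 and 426 FPKM in the Induced libraries, and Iigp1 from 6.48 ± 0.615 to 284 ± 74.2 FPKM. The log2 fold change of Ifitm1, 6.27, was 6.88 without Induced library B and 5.62 without Induced library C. Fam64a, the lymphotoxin gene Lta (10.4 ± 1.17 to 382 ± 97.0 FPKM), Ppp1r14c, the leukotriene B4 receptor gene Ltb4r1 (4.09 ± 1.17 to 148 ± 40.9 FPKM), Gzmb, the mitotic kinase genes Pbk and Aurkb, and Fgl2 (10.1 ± 0.635 to 232 ± 27.3 FPKM) made up the rest of the 10. The 10 largest falls were those of the globin genes Hbb-bs, Hba-a1, Hba-a2 and Hbb-bt, of Nr4a1 and Fos, of the adhesion gene Vcam1 (189 ± 59.1 to 0.144 ± 0.0195 FPKM), of Jchain, the joining chain of antibodies (224 ± 21.3 to 0.721 ± 0.435 FPKM), and of the complement genes C1qb and C1qc. The globin genes come in near-identical pairs, so the share of reads given to each copy is uncertain.

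Of 11 tested δ chain V segments, Trdv4 rose, 8 fell and 2 did not pass. Of 5 γ chain V segments 2 rose, 1 fell and 2 did not pass, and both counts were made after the values were seen. The δ segments counted here include those named for both the α and the δ chain, whose transcripts can also come from α chains. Scaling to the T cell identity genes gave 2 δ segments that rose and 5 that fell, and 3 γ segments that rose and 1 that fell. With TMM-like factors or quantile normalization 9 δ segments and 2 γ segments fell. Of 11 tested genes of the T cell receptor loci, Cd4 and Cd8, 5 rose, 2 fell and 4 did not pass (camera adjusted p = 0.66), and the counts adjusted over the list alone were the same. Trdv4 (ENSMUSG00000076867, a δ chain V segment on chromosome 14, 54074905 to 54075515) rose from 30.2 ± 3.69 to 589 ± 193 FPKM, with 712, 689 and 366 FPKM in Induced libraries A, B and C. The γ chain segment Tcrg-V6 (ENSMUSG00000076746, chromosome 13, 19190356 to 19190929) rose from 5.00 ± 1.03 to 51.7 ± 14.6 FPKM. Trac, the α chain constant region, fell from 134 ± 7.60 to 57.9 ± 14.8 FPKM and Cd4 from 3.01 ± 0.847 to 0.15 ± 0.055 FPKM. The constant regions of the β chain, the chain missing in these mice, were not analysed here. Of 20 T cell identity genes 12 fell, 2 rose and 6 did not pass (camera adjusted p = 0.0115, adjusted p = 0.295 with an estimated correlation), with the same counts adjusted over the list alone. The costimulatory receptor gene Cd28 (104 ± 10.2 to 10.9 ± 5.09 FPKM) and Cd6 (113 ± 7.87 to 20.2 ± 8.62 FPKM) fell most. Thy1 (27.6 ± 7.13 to 40.5 ± 1.35 FPKM) and Lcp2 (135 ± 5.67 to 156 ± 11.7 FPKM) rose, and the call of Lcp2 (adjusted p = 0.0394) was lost without Initial library A (adjusted p = 0.112), Initial library C (0.0853), Induced library A (0.127) or Induced library B (0.144).

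**Figure D2:**
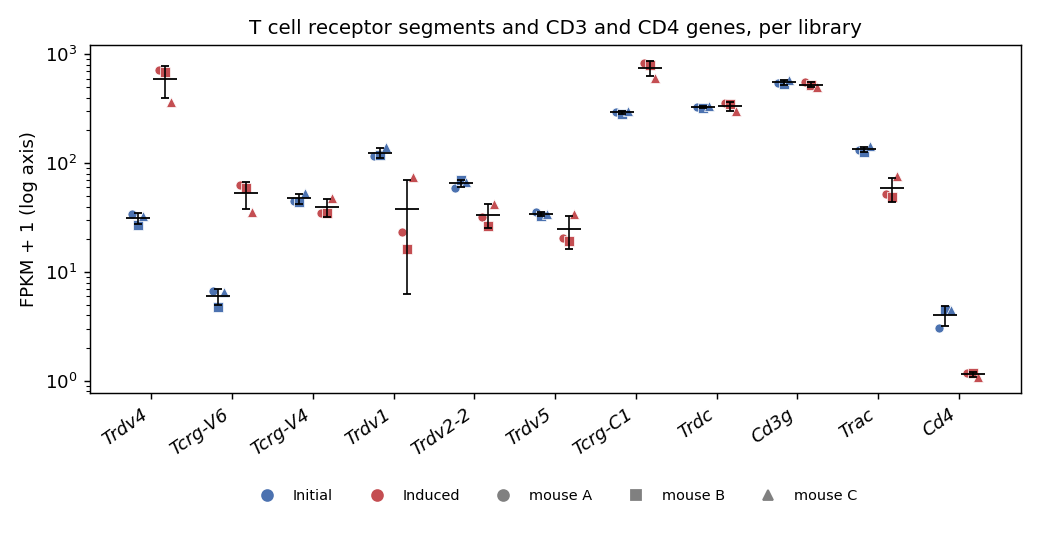
FPKM + 1 on a log axis of T cell receptor segments, Trdc, Cd3g, Trac and Cd4 in 3 Initial (blue) and 3 Induced (red) libraries; marker shapes give the mouse, horizontal bars the mean and error bars the SD, and Tcrg-V4, Trdv1, Trdv2-2, Trdv5, Tcrg-C1, Trdc and Cd3g were chosen after their values were seen. Trdv4 and Tcrg-V6 sit higher in all Induced libraries, with library C the lowest of them, while Trdc stands at 327 ± 7.24 and 335 ± 31.7 FPKM.

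Proliferation genes rose together. All 30 genes of the cell cycle list rose (camera adjusted p = 3.6e-15, adjusted p = 0.295 with an estimated correlation), as with Aurkb (3.88 ± 0.267 to 102 ± 11.5 FPKM) and the cyclin gene Ccnb2 (7.51 ± 1.12 to 171 ± 14.2 FPKM). Of 21 glycolysis genes 17 rose and none fell (camera adjusted p = 1.3e-06, adjusted p = 0.272 with an estimated correlation). The lactate exporter gene Slc16a3 went from 6.80 ± 0.649 to 142 ± 19.7 FPKM, and Tpi1, which overlaps the less abundant Spsb2 on the other strand, from 46.2 ± 3.28 to 479 ± 4.08 FPKM. In the cholesterol and fatty acid synthesis list 17 of 23 genes rose and 2 fell (camera adjusted p = 0.000303, adjusted p = 0.295 with an estimated correlation). The sterol enzyme gene Sqle (9.15 ± 0.907 to 61.8 ± 6.28 FPKM) rose, and the desaturase gene Scd1 (6.86 ± 0.658 to 0.312 ± 0.102 FPKM) and Insig1 (24.4 ± 2.46 to 11.4 ± 0.976 FPKM) fell. Of 16 hypoxia genes 11 rose and 2 fell, or 12 rose adjusted over the list alone (camera adjusted p = 0.00613, adjusted p = 0.295 with an estimated correlation), with Bnip3 (6.56 ± 0.129 to 88.1 ± 4.51 FPKM) and P4ha2 (0.389 ± 0.164 to 6.20 ± 0.944 FPKM) higher and Vegfa (3.27 ± 0.591 to 0.759 ± 0.154 FPKM) and Bnip3l (110 ± 3.31 to 55.8 ± 2.52 FPKM) lower. With libraries scaled to the T cell identity genes the calls of Insig1 (adjusted p = 0.109) and Bnip3l (0.448) were lost. Adjusted over the list alone, the counts of the other lists of this paragraph were the same.

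Mitochondrial and biosynthetic lists held both rises and falls. Of 31 oxidative phosphorylation genes 17 rose, 3 fell and 11 did not pass (camera adjusted p = 0.0498, adjusted p = 0.733 with an estimated correlation). This call was also lost without Initial library A (adjusted p = 0.0676), Initial library B (0.0739) or Induced library C (0.107). The cytochrome oxidase genes Cox5a (91.2 ± 11.8 to 230 ± 0.876 FPKM) and Cox7a2 (48.5 ± 13.1 to 79.8 ± 1.32 FPKM) rose, and Uqcrfs1 (123 ± 6.33 to 96.5 ± 5.92 FPKM) and Atp5a1 (434 ± 22.4 to 370 ± 17.8 FPKM), which overlaps Haus1 on the other strand, fell. The call of Atp5a1 was lost without Initial library A (adjusted p = 0.0675), Induced library A (0.0787) or Induced library B (0.0748). In the fatty acid oxidation list 11 of 20 genes rose and 6 fell (camera adjusted p = 0.488), among them Cpt2 (7.35 ± 0.777 to 12.7 ± 0.901 FPKM) and Etfb (55.3 ± 2.95 to 83.4 ± 3.76 FPKM) higher and the lipid receptor gene Cd36 (7.73 ± 0.970 to 1.25 ± 0.420 FPKM) and Eci1 (22.0 ± 2.02 to 14.4 ± 3.95 FPKM) lower. The call of Eci1 was lost without Initial library C (adjusted p = 0.0593). Of 25 ribosome biogenesis genes 4 rose and 4 fell, or 3 fell adjusted over the list alone (camera adjusted p = 0.971), with Nhp2 (27.7 ± 3.45 to 50.9 ± 6.90 FPKM) and Dkc1 (43.1 ± 2.65 to 71.1 ± 10.3 FPKM), which overlap Rmnd5b and Mpp1 on the other strand, higher and Ncl (159 ± 8.17 to 109 ± 17.1 FPKM) and Npm1 (284 ± 25.1 to 198 ± 34.0 FPKM) lower. With libraries scaled to the T cell identity genes, Uqcrfs1, Atp5a1, Ncl and Npm1 rose. Eci1 had a log2 fold change of 0.22 (adjusted p = 0.155). With libraries scaled to the CD3 chains and Trdc, Atp5a1 (-0.0043, adjusted p = 0.963), Uqcrfs1 (-0.12, adjusted p = 0.218) and Eci1 (-0.39, adjusted p = 0.0726) did not pass. The ribosome biogenesis list was called with libraries scaled to the T cell identity genes (adjusted p = 0.0491). Of 25 genes of the unfolded protein and amino acid response 17 rose and 7 fell, or 18 rose adjusted over the list alone (camera adjusted p = 0.0643, and 0.0012 without a filter on low values). The asparagine synthetase gene Asns (0.999 ± 0.130 to 22.8 ± 1.11 FPKM) and Mthfd2 (18.8 ± 1.16 to 60.0 ± 3.16 FPKM) rose, and Dnajb9 (199 ± 4.05 to 40.0 ± 5.09 FPKM) and Slc3a2 (397 ± 53.2 to 89.1 ± 11.2 FPKM) fell. For the remaining lists of this paragraph the counts adjusted over the list alone were the same.

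Genes of naive and recirculating lymphocytes fell. In that list 20 of 22 genes fell and 2 did not pass (camera adjusted p = 4.5e-09, adjusted p = 0.295 with an estimated correlation), led by the transcription factor gene Klf3 (125 ± 11.1 to 3.23 ± 0.753 FPKM) and Dapl1 (36.7 ± 5.77 to 0.277 ± 0.247 FPKM). All 22 tested immediate early genes fell (camera adjusted p = 4.9e-12, adjusted p = 0.221 with an estimated correlation), and Fos went from 308 ± 53.4 to 0.829 ± 0.211 FPKM. Of 21 activation and checkpoint genes 13 fell and 5 rose (camera adjusted p = 0.0521). That list was called without Initial library B (adjusted p = 0.0419), Induced library A (0.037) or Induced library B (0.0299), and with both scalings to T cell genes. It was also called with the filter at FPKM 5 (adjusted p = 0.0172), a pseudocount of 5 (0.0451), quantile normalization (0.0469) or genes of other cell types left out (0.0391). The interleukin-2 receptor gene Il2ra (5.64 ± 0.555 to 74.5 ± 3.38 FPKM) and Havcr2 (4.94 ± 1.61 to 15.3 ± 3.66 FPKM) rose, and the activation marker gene Cd69 (537 ± 65.9 to 26.3 ± 1.63 FPKM) and Tox (57.0 ± 5.37 to 4.07 ± 1.89 FPKM) fell. Immunoglobulin genes, a sign of B cells, took 1.23 to 1.56% of the summed FPKM in the Initial libraries and 0.0205 to 0.0525% in the Induced libraries, and moved with the groups in the same way as these 3 lists. Adjusted over the list alone, the counts of the 3 lists were the same.

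The series title concerns the recruitment of myeloid cells. Of 30 chemokine and myeloid growth factor genes fixed beforehand 13 passed the filter, of which 4 rose and 9 fell (camera adjusted p = 0.138), with the same counts adjusted over the list alone. The list was called as lower with libraries scaled to the CD3 chains and Trdc (adjusted p = 0.0273) or to the T cell identity genes (adjusted p = 0.00056). All 22 tested macrophage and monocyte genes fell as well, and which cells the 9 falls came from was not tested. Csf2 and Ccl1 (0.0991 ± 0.102 to 1.96 ± 1.27 FPKM) had the largest rises, and Xcl1 and Ccl5 the largest falls. Of 19 integrin and chemokine receptor genes 7 rose, 7 fell and 5 did not pass (camera adjusted p = 0.682), with the same counts adjusted over the list alone. Ccr2 (19.0 ± 1.44 to 226 ± 13.4 FPKM) and Cxcr6 (116 ± 31.2 to 1204 ± 221 FPKM), receptors for inflammatory chemokines, rose. Ccr9 (29.1 ± 3.99 to 0.254 ± 0.0902 FPKM), a gut homing receptor gene, and Cxcr5 (26.5 ± 2.13 to 0.789 ± 0.538 FPKM), a receptor gene of B cell follicles that overlaps Bcl9l on the other strand, fell. Of 30 interferon-stimulated genes 11 rose, 14 fell and 5 did not pass, or 12 rose adjusted over the list alone (camera adjusted p = 0.553). The GTPase genes Igtp (72.1 ± 6.28 to 1107 ± 146 FPKM), which overlaps Irgm2 on the same strand, and Gbp2 (56.9 ± 1.92 to 359 ± 37.0 FPKM) rose, while Oasl1 (7.23 ± 0.973 to 0.336 ± 0.202 FPKM) and Ifit3 (18.4 ± 0.372 to 2.40 ± 0.378 FPKM) fell.

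Some lists of other spleen cells were lower after culture. All 22 tested macrophage and monocyte genes fell (camera adjusted p = 3.8e-11, adjusted p = 0.295 with an estimated correlation), with C1qb at 128 ± 32.0 and 0.193 ± 0.0262 FPKM. All 16 tested B cell genes fell (camera adjusted p = 1.0e-07, adjusted p = 0.311 with an estimated correlation), with Ly6d at 49.7 ± 3.75 and 2.64 ± 1.3 FPKM and Fcer2a at 15.4 ± 2.08 and 0.398 ± 0.304 FPKM. Of 11 erythroid genes 9 fell (camera adjusted p = 7.2e-05, adjusted p = 0.295 with an estimated correlation), with Hbb-bs at 567 ± 154 and 0.543 ± 0.0755 FPKM, and Tfrc, the transferrin receptor gene that dividing cells also use, rose from 17.3 ± 1.08 to 48.2 ± 1.48 FPKM. Of 14 dendritic cell genes 11 fell and 2 rose, or 12 fell adjusted over the list alone (camera adjusted p = 0.000646, adjusted p = 0.272 with an estimated correlation). Ccr9 and the MHC class II gene H2-Eb1 (239 ± 26.0 to 10.7 ± 4.32 FPKM) fell, and Batf3 (1.23 ± 0.473 to 4.85 ± 2.35 FPKM) and Xcr1 (0.762 ± 0.145 to 2.35 ± 0.235 FPKM) rose. Of 13 natural killer and innate lymphoid genes 12 fell and 1 rose (camera adjusted p = 0.000735, adjusted p = 0.295 with an estimated correlation), with the adaptor genes Fcer1g (63.1 ± 10.8 to 1.82 ± 0.613 FPKM) and Tyrobp (37.5 ± 6.94 to 0.708 ± 0.324 FPKM) among the falls. The lists of plasma cells (8 tested, 2 rose and 3 fell, camera adjusted p = 0.64) and mast cells and basophils (5 tested, 2 rose and 2 fell, camera adjusted p = 0.847) were not called. Among plasma cell genes Jchain and Mzb1 (10.8 ± 0.485 to 0.940 ± 0.634 FPKM) fell, and Prdm1 (3.11 ± 0.922 to 6.45 ± 1.59 FPKM) and Txndc5 (49.1 ± 2.39 to 68.9 ± 3.76 FPKM) rose. In the mast cell and basophil list Prss34 (0.0132 ± 0.0229 to 6.21 ± 3.85 FPKM) and Cpa3 (0.444 ± 0.182 to 1.69 ± 0.353 FPKM) rose, and Kit (10.5 ± 1.93 to 4.38 ± 1.5 FPKM) and Hdc (2.61 ± 0.435 to 0.774 ± 0.223 FPKM) fell. The call of Kit was lost with libraries scaled to the T cell identity genes (adjusted p = 0.294). The neutrophil list had 2 tested genes, Ltb4r1 and Mmp9 (3.09 ± 0.908 to 33.5 ± 21.3 FPKM), both higher after culture. Without Induced library C the log2 fold change of Mmp9 went from 2.83 to 3.5. The stromal list had 2 tested genes, of which Pdgfrb (0.731 ± 0.145 to 5.06 ± 1.46 FPKM) rose. The platelet list had 1, Clec1b, with 4.23 ± 1.39 FPKM before culture and no listed value after it. Apart from dendritic cells, the counts adjusted over the list alone were the same for the lists of this paragraph. No list call held with an estimated correlation. The median and mean log2 fold change differed in sign for plasma cells (0.07 and -1.12), mast cells and basophils (-0.30 and 0.23) and integrins and chemokine receptors (0.01 and -0.41). Camera placed the mast cell and ribosome biogenesis lists lower, although their means were 0.23 and 0.04, and fry, which tests whether the genes of a list move one way on balance, placed the type 1 list higher, although its mean was -0.27.

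**Figure D3:**
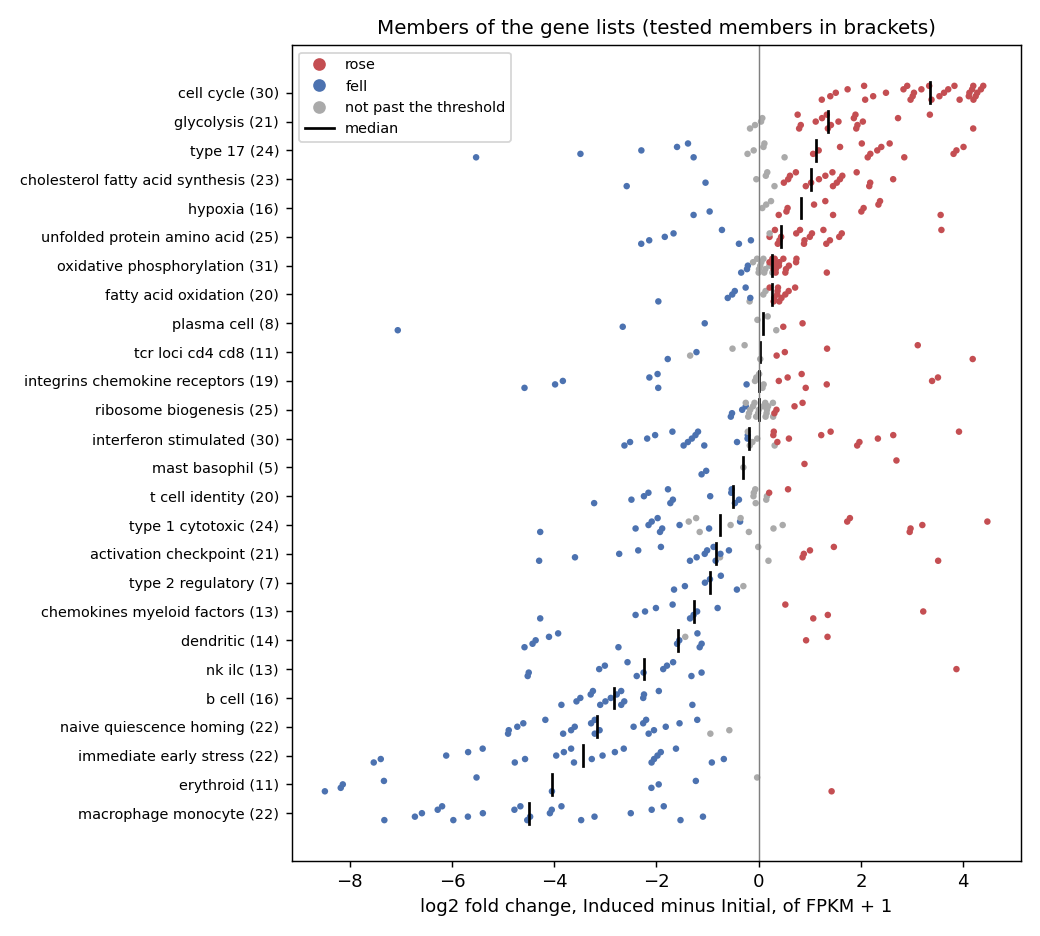
Log2 fold change, Induced minus Initial on the FPKM + 1 scale, of each tested member of the 26 lists with at least 5 tested genes; red members rose, blue fell and grey did not pass the test, and black bars are list medians. All 30 cell cycle genes lie to the right of 0, and all 22 macrophage and all 22 immediate early genes to the left; with libraries scaled to the T cell identity genes, the median of all genes moves from 0.03 to 0.81.

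The number of genes detected depended on the limit. With a limit of FPKM 1, the Initial libraries held 10998 ± 68.6 genes and the Induced libraries 10485 ± 11.2, a difference of -513 genes. The difference was -1340 genes with a limit of FPKM 0.1 and -94 genes with a limit of FPKM 5. A two-sided exact permutation test gave p = 0.1 at each limit, the smallest value that 3 against 3 libraries allow. Genes of other cell types moved with these counts: 117 immunoglobulin V segments had an FPKM of at least 1 in all Initial libraries and 1 had in all Induced libraries. With immunoglobulin genes, globins and the lists of other cell types left out, a choice made after the data were seen, the differences were -332, -1216 and 52 genes at limits of FPKM 1, 0.1 and 5 (exact permutation test, p = 0.1, 0.1 and 0.2).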

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

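The scalings to T cell genes and the fit without genes of other cell types were chosen after the data were seen. Between 7103 (without Induced library A) and 7916 genes were called with 1 library left out, and between 2783 and 2968 at least 2-fold. The alternatives set beforehand that changed the filter or the scale gave 6175 to 9189 called genes, and none called a gene in the direction opposite to the deposited scale. The count of at least 2-fold changes was 1604 with a pseudocount of 5, since a larger pseudocount shrinks fold changes. With libraries scaled to the T cell identity list, 5273 genes changed at least 2-fold, 8183 rose and 1436 fell, 944 of the calls turned to the opposite direction, and the median log2 fold change moved from 0.03 to 0.81. That list itself fell, with 12 of its 20 genes, so the scaling raises all other genes by construction. Scaled to the CD3 chains and Trdc, 5384 genes rose and 2676 fell, and the median was 0.23. The scaling to T cell identity genes turned Uqcrfs1 (0.52), Atp5a1 (0.64), Ncl (0.32) and Npm1 (0.34) into rises past the threshold and gave Eci1 0.22, which did not pass (adjusted p = 0.155). It also ended the calls of Ccl5, Bnip3l, Insig1 and Kit, and the scaling to the CD3 chains and Trdc those of Atp5a1, Uqcrfs1 and Eci1. The call of Lcp2 was lost with TMM-like factors (adjusted p = 0.13), rescaling to a common sum (0.0658), quantile normalization (0.111), no filter (0.064) and an ordinary moderated test (0.0623). Camera called 14 of 26 lists, and none with an estimated correlation. Fry called 22 of the 26, among them all of the 14. With genes of other cell types left out 19 lists were tested, 9 of them from the 14, and 8 of these 9 were called, as was the activation and checkpoint list. The estimated correlations run up to 0.81. The mean difference between the interferon-stimulated list and other genes turned to 0.155 with a pseudocount of 5 and 0.0905 with the filter at FPKM 5, and that of fatty acid oxidation to -0.00080 after quantile normalization. That of ribosome biogenesis ranged from -0.0449 to 0.153 with 1 library left out (without Induced library C and Induced library B), and was 0.162 with libraries scaled to the T cell identity list, where the list was called (adjusted p = 0.0491). The cause of these reversals, none of them of a called list, was not tested. Oxidative phosphorylation lost its call with the filter at FPKM 5 (adjusted p = 0.0884), TMM-like factors (0.0601), quantile normalization (0.0812) and without genes of other cell types (0.0664), in a range of 0.000134 to 0.733 over its alternatives. Of 106 genes the rule takes, 93 kept their call under every alternative in which they were tested. With the filter at FPKM 5, 90 of the 106 were tested, and with genes of other cell types left out 77. With the mouse as a block 7943 genes were called, and Ifng and Tbx21, at adjusted p-values of 0.0323 and 0.0052, were the only named genes or lists whose call it changed. The difference in genes detected was -1339.67 at FPKM 0.1 and -94 at FPKM 5, and -548 to -480 with 1 library left out. With genes of other cell types left out it was -332, and -1215.67 at FPKM 0.1 and 52 at FPKM 5. The ratio of means moved by over 1.5 times without Induced library A for Il22 (30.3-fold to 47.2-fold lower), Fcer2a (38.7-fold to 65.4-fold), Cxcr5 (33.7-fold to 54.7-fold) and Dapl1 (132-fold to 205-fold), and without Induced library B for Ccl1 (19.8-fold to 12.4-fold higher). Without Induced library C the ratio moved by over 1.5 times for Ifitm1 (175-fold to 93.5-fold higher) and Ccl5 (4.31-fold to 8.43-fold lower). For Dapl1 it moved by 1.5 times there (132-fold to 88.2-fold lower). Prss34, and Ccl1 without Initial library B, had Initial means too low for a fold. The alternatives set beforehand for raw counts (DESeq2, and edgeR without a filter) were not run, because the tables hold no counts. At the estimated depth, 3 fragments of a 2 kb transcript amount to an FPKM of 0.0553 to 0.0702, so lower values were not distinguishable from 0.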

Other observations

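The gene families, the genes named here that stand outside the rule and all tests of explanations were chosen after the values were seen. All 16 tested interferon-inducible GTPase genes (Gbp, Irgm, Iigp1, Igtp and Tgtp) rose, with a median log2 fold change of 2.47, and did so under each of the 5 other scalings run. In other interferon-induced families, of 5 Ifit genes 3 fell and 2 did not pass, and of 7 Oas genes 5 fell and 2 did not pass. The scalings matter here: 1 Ifit gene and 2 Oas genes rose with libraries scaled to the CD3 chains and Trdc, and 1 Oas gene after quantile normalization. Scaled to the T cell identity list, 2 Ifit and 3 Oas genes rose, and the median of the Oas genes was 0.33. All 6 tested S100 genes rose under every scaling run, S100a4 from 98.6 ± 16.1 to 813 ± 45.6 FPKM. The cytokine gene Tnf rose from 10.5 ± 1.33 to 92.1 ± 28.6 FPKM and Ltb from 243 ± 45.8 to 542 ± 29.5 FPKM.

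Of 19 tested Klr genes, receptors of natural killer and T cells, 15 fell and 2 rose (with libraries scaled to the T cell identity list 11 fell, to the CD3 chains and Trdc 12 and after quantile normalization 14, and 2 rose in each), and Klra1 went from 13.0 ± 0.712 to 0.426 ± 0.350 FPKM. All 8 tested MHC class II genes fell under every scaling run, with a median log2 fold change of -3.44. Induced library C stood apart from A and B in several genes. Trdv1 had 22.5, 15.2 and 73.5 FPKM in Induced libraries A, B and C, and Ly6c2 had 308, 119 and 1082 FPKM.

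Markers of B cells, macrophages and erythroid cells fell. Of 49 tested members of the 3 lists, 47 fell, or 95.9%, and none of the 49 stands in another list, although 13 had an FPKM of at least 1 in all Induced libraries. With libraries scaled to the CD3 chains and Trdc their median log2 fold change was still -3.28. That scaling moved the median of all genes only from 0.03 to 0.23, and a shift of that size leaves the fall in place. It takes the level of these T cell genes per cell as steady, which was not tested. Loss of immunoglobulin transcripts by the T cells themselves is argued against by 117 V segments with an FPKM of at least 1 in all Initial libraries, against 1 in all Induced libraries. A candidate explanation is that the Initial libraries held RNA of other spleen cells, despite a sort whose gate is not given in the sources used here: Igkc stood at 1574 ± 143, Hbb-bs at 567 ± 154 and Lyz2 at 184 ± 83.0 FPKM there. Culture and the second purification step differ between the groups as well, and their parts were not tested.

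Il23r and Il1r1 rose. More T cell RNA in the Induced libraries is argued against by the median log2 fold change of Cd3d, Cd3e, Cd3g, Cd247 and Trdc, -0.10 (SD 0.25 over the 5 genes), where the smaller rise of the 2 genes was 2.18. That holds only if the level of these 5 genes per T cell was steady in culture, which was not tested. Cd3e (-0.53) and Cd3d (-0.47) were called lower, while Cd3g, Cd247 and Trdc did not pass. Expansion of cells that use Tcrg-V6 and Trdv4 cannot be told apart from induction within each cell, which was not tested. The smaller rise of these segments exceeded the larger rise of the 2 genes by 0.71 (SE 0.29). This SE takes the rises as independent, although they were measured in the same libraries. The segments were picked for their rise, so this difference does not support expansion as the source of the rise of Il23r and Il1r1. Trdv4 made up 4.92, 3.73 and 4.30% of the summed FPKM of 15 δ chain V segments in Initial libraries A, B and C. In the Induced ones it made up 79.6, 81.1 and 52.0%. These 15 include segments named for both the α and the δ chain, so α chain transcripts can add to the sum. On the deposited scale 8 of the 10 other tested δ segments fell and 0 rose, while Trdc stood at 327 ± 7.24 and 335 ± 31.7 FPKM. The transcripts of these V segments thus shifted towards Trdv4, and the part of α chain transcripts in that shift was not tested. How much of the rise of Il23r and Il1r1 goes with that shift was not tested.

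Immediate early genes fell, in 22 of 22 tested members. Their median log2 fold change was still -3.26 with libraries scaled to the CD3 chains and Trdc. That scaling moved the median of all genes only from 0.03 to 0.23, and a shift of that size leaves the fall in place. Whether these T cell genes were steady per cell was not tested. Between Initial libraries the macrophage list differed by medians of 0.74 (A over C), 0.54 (B over C) and 0.20 (A over B). The immediate early list differed by 0.18, 0.23 and -0.02, differences of -0.56, -0.31 and -0.22. Its quartiles ran from 0.0013 to 0.30, from -0.09 to 0.43 and from -0.14 to 0.11. Those of the macrophage list ran from 0.66 to 0.86, from 0.44 to 0.66 and from 0.15 to 0.28. The quartile ranges did not overlap in any pair, although the pairs share libraries. This argues against macrophages as the only source of the immediate early list, if they responded alike in each mouse. With 1 library per mouse, a different response of the macrophages in each mouse is not separated from another source. A part from macrophages stays open. Handling of the freshly sorted cells cannot be told apart from the state of the cells before culture, since all Initial libraries were fresh and all Induced ones cultured.

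The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 7931 genes and 2838 at least 2-fold, and 1 of 10 splits, the real one, gave as many, with 0 as the highest of the others in both counts. For the lists the real split called 14 and the highest other 15, and 5 of 10 splits gave at least 14. The other splits set 2 libraries of a group and 1 of the other against the reverse, so they carry part of the difference between the groups. That difference also widens the spread within each side, so few gene calls could arise in them, and the 0 says little.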
